A study of Mus musculus with 162 samples.

How the data were processed

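RNA from cortex, hippocampus and cerebellum of the right hemisphere was sequenced in mice given an Hdac2 ASO or a scrambled ASO, with 3 mice per group at each of 9 time points. Per the labels, RNA came from an AllPrep kit, libraries were ribosome-depleted total RNA (TruSeq Stranded with Ribo-Zero Gold), and either a HiSeq or a NextSeq instrument was used. The submitters' processing notes name TopHat, featureCounts and edgeR with standard settings, and also Cuffdiff, without versions, and the build GRCm38.p3. Gene coordinates and symbols come from a GENCODE annotation of GRCm38, of which GRCm38.p3 is a patch release that leaves chromosome coordinates as they are. It named 45143 genes by ID, and 18 were named by the files alone.

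The deposited data, in 27 files with 1 per tissue and time point, hold the authors' edgeR results and no value per library. Per the file headers these are a log2 fold change, an average log2 CPM (logCPM, counts scaled to library size), a likelihood-ratio score (LR), a p-value and an FDR. It was checked that the authors' deposited p-value is the upper tail of a chi-square with 1 degree of freedom at the LR score, and that the FDR is the Benjamini-Hochberg value over all genes of a table. The headers do not state the direction of the log2 fold change in the authors' deposited tables. Hdac2 is negative in 27 of 27, so a negative value is read as lower with the Hdac2 ASO, which makes the direction of Hdac2 itself an assumption and not a result. Library size was inferred from the lowest logCPM of each table, assuming the edgeR default prior count of 2 for the authors' runs, as about 8310000 to 43300000 reads, and depth per single library is unknown.

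The tests written before the data were examined needed counts per library. Where only the authors' statistics are held, the plan was to describe them without a test, and this was done for each time point. Genes were called higher or lower at the authors' FDR under 0.05. The comparisons that combine time points, and camera and fry for lists, were planned for counts per library. The form they have here, on the authors' log2 fold changes with the 9 time points as replicates, was chosen after the data were seen: other mice were used at each time point, but the 3 tissues are taken to come from the same mice. The change of the ASO effect over time, gene by gene, was not analysed here.

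For averages over time, limma 3.58.1 (R 4.3.3) tested the mean of the 9 log2 fold changes with trend and robust options, in genes with a mean logCPM of at least 1. It was chosen as the form nearest to the plan after these had all been run: limma with another trend covariate by mistake, limma with and without the robust option on log2 fold changes and on signed square roots of LR, limma with table weights, and the sum of signed roots of LR with and without division by inflation. Hdac2 was tested by exact sign-flip and exact permutation tests, two-sided. Recovery was tested on simulated data, in 10 draws with 200 changed genes each. Gene lists and cell type markers were fixed before the data were examined and tested by camera (preset and estimated correlation), fry and exact sign-flip tests of the list median, over all lists and tissues. They had first been explored on scaled signed roots. Camera and the named averages were also computed without each time point in turn, which was chosen after the results were seen. Relations of Hdac2 with weeks (3) and with list medians (12) were computed over 9 time points. They were chosen after the data were seen, and the largest gap between Hdac2 values was compared with that of 9 uniform values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

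Named genes were set by a rule: Hdac2, Hdac1 and Hdac3, the 12 highest and 12 lowest averages per tissue past the threshold with the sign of the average in at least 7 of 9 time points, the 2 highest and 2 lowest log2 fold changes per table among genes past the threshold with logCPM of at least 1, 4 members per list, and genes past the threshold in all 3 tissues. Predicted genes were left out where enough other genes remained. Its condition that libraries of the 2 groups do not overlap could not be checked without values per library. As the limma test called no gene, the averages named are those called by the sum of signed roots with LR divided by inflation. The other genes, among them further list members and C4b, Lyz2 and Gfap at single time points, Prph and Slc5a7, were chosen after their values were seen. The values of some single genes are not reported here. C4b, the globin genes, the kallikrein genes and the 7SL copies have close paralogs, and reads shared between them could not be told apart here. Left out were values per mouse, spreads and batches (an instrument per library was not used here), none of which the tables hold.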

Results

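RNA was sequenced from the cortex, hippocampus and cerebellum of mice given an antisense oligonucleotide (ASO), a short synthetic nucleic acid strand that binds a chosen RNA. The ASO was directed at Hdac2, which encodes histone deacetylase 2, an enzyme that removes acetyl groups from histones. Control mice received a scrambled ASO. There were 3 mice per group at each of 9 time points, which were 3 days and 2, 4, 8, 16, 32, 40, 48 and 52 weeks, and other mice were used at each time point. The libraries are summarised in 27 tables of the authors' statistics, 1 per tissue and time point. Library sizes are not stated in these tables. The lowest logCPM of each table gave about 8310000 to 43300000 reads per library, if edgeR's default prior count of 2 was used. The tables hold no value per mouse, so the spread between replicates is not given here beside any fold change.

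The first question was how far Hdac2 RNA fell and for how long. Hdac2 (ENSMUSG00000019777) lies on chromosome 10 from 36974544 to 37001889 on the + strand of GRCm38. Its log2 fold change was below 0 in 27 of the 27 authors' deposited tables, and it passed FDR 0.05 in 13 of them. The unadjusted edgeR p was under 0.05 in 24 of the 27, with 8 of 9 in cortex, 9 of 9 in hippocampus and 7 of 9 in cerebellum. A time point that did not pass the FDR therefore does not show a return to the scrambled level. In cortex the authors' deposited tables gave Hdac2 at 35.4% of the scrambled level at 2 weeks (log2 fold change -1.50, FDR 6.81e-45). It stood at 26.3% at 4 weeks (-1.93, FDR 4.14e-41) and at 20.2% at 8 weeks (-2.31, FDR 2.14e-24) in the authors' deposited tables. The values were 29.3% at 16 weeks (-1.77, FDR 2.41e-32) and 59.6% at 32 weeks (-0.75, FDR 4.55e-08) in the same authors' deposited tables. The remaining cortex time points did not pass, with 26.9% at 3 days (FDR 0.213), 58.0% at 40 weeks (FDR 0.285), 86.2% at 48 weeks and 77.7% at 52 weeks (FDR 1 for both) in the authors' deposited tables.

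Hippocampal Hdac2 passed at 3 days (33.5%, FDR 0.0127), 2 weeks (49.6%, FDR 1.35e-12) and 4 weeks (34.5%, FDR 5.15e-13) in the authors' deposited tables. It also passed at 8 weeks (35.6%, FDR 8.44e-06) and 16 weeks (31.5%, FDR 1.35e-28) in the authors' deposited tables. From 32 weeks on Hdac2 stood between 66.6% and 76.7% of the scrambled level in hippocampus, and none of these 4 time points passed in the authors' deposited tables. Their unadjusted edgeR p-values were 0.000513, 0.00427, 0.00884 and 0.00298 at 32, 40, 48 and 52 weeks. Cerebellar Hdac2 passed at 4 weeks (59.4%, FDR 3.75e-05), 8 weeks (55.3%, FDR 5.08e-28) and 16 weeks (64.6%, FDR 4.99e-06) in the authors' deposited tables. It stood at 69.7% at 3 days (FDR 0.541) and at 90.7% at 52 weeks (FDR 1) in cerebellum in the authors' deposited tables. Hdac1, the close paralog that shares complexes with HDAC2, ranged from -0.35 to 0.30 in log2 and passed in 0 of the authors' 27 deposited edgeR tables, with an unadjusted p under 0.05 in 2. Hdac3, the catalytic subunit of the NCoR complex, ranged from -0.29 to 0.20 and passed in 0 of the authors' 27 deposited edgeR tables, with an unadjusted p under 0.05 in 1.

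**Figure D1:**
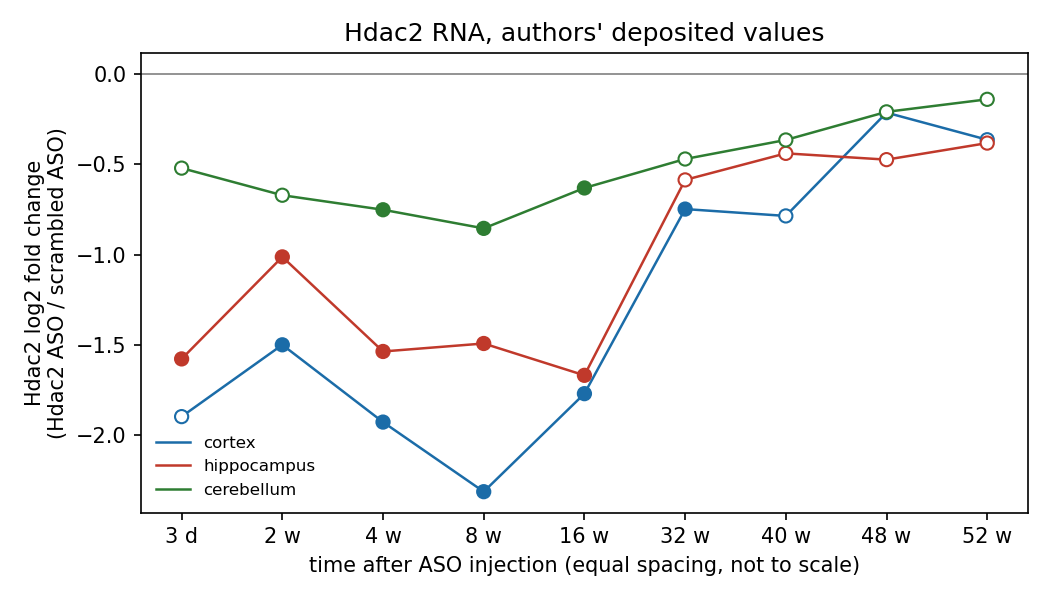
Hdac2 log2 fold change (Hdac2 ASO against scrambled ASO, 3 mice per group) at 9 time points in cortex, hippocampus and cerebellum, from the authors' deposited tables, with filled points where the authors' FDR is under 0.05. Hdac2 is lowest in cortex at 8 weeks (-2.31) and nearest to 0 in cerebellum at 52 weeks (-0.14).

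Averaged over the 9 time points, the Hdac2 log2 fold change was -1.28 in cortex, -1.02 in hippocampus and -0.51 in cerebellum. Each was below 0 at 9 of 9 time points (exact sign-flip test, two-sided p = 0.0039, the smallest that 9 tables allow). The mean of 40, 48 and 52 weeks was higher than that of 2, 4 and 8 weeks by 1.46 in cortex, 0.91 in hippocampus and 0.52 in cerebellum. For each tissue the exact permutation p was 0.1, the smallest that 3 against 3 tables allow, so this difference could not pass 0.05. Over the 9 tables the Hdac2 fold change was nearer to 0 at later weeks in all 3 tissues. Pearson's r was 0.92 in cortex (permutation p = 0.00188), 0.87 in hippocampus (p = 0.00986) and 0.88 in cerebellum (p = 0.00215), with adjusted p of 0.00323, 0.00986 and 0.00323 over the 3 tissues. Spearman's rho was 0.77 in each tissue (exact permutation p = 0.0214, adjusted p = 0.0214). Without the 2 time points farthest from the median, r was 0.83, 0.79 and 0.71. The largest gap between neighbouring Hdac2 values was 34.0%, 37.3% and 21.8% of their range, and 42.7%, 30.3% and 95.6% of sets of 9 uniform values leave a gap as large. The values are therefore not treated as separate clusters, and r was not computed on each side of the gap.

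Hdac2's decrease was larger in cortex than in cerebellum by 0.77 in mean log2 (difference -0.77, 9 of 9 time points, exact sign-flip p = 0.00391, adjusted p = 0.00586 over 3 pairs). Hippocampus minus cerebellum gave -0.51 (9 of 9, exact sign-flip p = 0.00391, adjusted p = 0.00586). Cortex minus hippocampus gave -0.26 (7 of 9, exact sign-flip p = 0.0352, adjusted p = 0.0352), and this did not pass without any 1 of 3 days, 2, 4, 8 or 40 weeks (p = 0.0703 each). Limma on the paired differences called 0 genes at adjusted p 0.05 for all 3 pairs, Hdac2 included. Counts at an unadjusted p under 0.05 were 567 of 13682 genes for cortex minus hippocampus, 274 of 13369 for cortex minus cerebellum and 158 of 13153 for hippocampus minus cerebellum.

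The nearest protein-coding genes to Hdac2 are Hs3st5, 140147 bp towards lower coordinates, and Marcks, 131486 bp towards higher coordinates. With Frk, Amd2, Rfpl4b and Lama4, they are the 3 nearest on each side. Of these 6, only 3 in cortex, 2 in hippocampus and 3 in cerebellum were tested (mean logCPM of at least 1). In cortex they were Marcks, Hs3st5 and Lama4. The tested genes give 72 values over the authors' deposited edgeR tables, and the others are not covered. Of these, 0 passed, 4 were higher and 1 lower when adjusted over the list alone, and 9 had an unadjusted p under 0.05. The other 10 class I, II and IV deacetylase genes give 270 values, of which 0 passed in the authors' deposited edgeR tables. Adjusted over the list alone, 2 were higher and 3 lower, and 17 had an unadjusted p under 0.05. Among 32 genes for partners of HDAC1 and HDAC2 in the Sin3, NuRD and CoREST complexes, 2 of 864 values were higher and 0 lower, or 9 and 1 adjusted over the list alone. DNA and histone methylation and acetylation enzymes had 2 of 711 values higher and 0 lower, or 8 and 6 adjusted over the list alone. Synapse and memory genes had 6 of 855 higher and 2 lower, or 27 and 10 adjusted over the list alone.

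The next question was which other genes changed at each time point. In cortex, genes of reactive astrocytes and of activated microglia were among those that rose between 2 and 16 weeks. At 4 weeks Clec7a (log2 fold change 4.23, FDR 1.03e-05), which encodes the receptor dectin-1, and Itgax (3.65, FDR 0.000684), the integrin CD11c, rose most among genes with a logCPM of at least 1 in the authors' deposited table. Itgax (4.21) and Clec7a (3.67) again led at 8 weeks, and Gpnmb (3.34), Lyz2 (3.21, lysozyme), Cd74 (2.31, the MHC class II invariant chain), Cd68 (1.48, a lysosomal protein of phagocytes) and C1qa (1.32, a complement subunit) also rose in the authors' deposited table. Complement C4b rose at 2, 4, 8 and 16 weeks, by 1.00, 1.74, 2.50 and 1.96, in the authors' deposited tables. Gfap, the astrocyte filament gene, rose at 2, 4 and 8 weeks by 0.75, 1.43 and 1.72, and its 1.07 at 16 weeks did not pass (FDR 0.0569) in the authors' deposited tables. P2ry12 (-0.11), Tmem119 (0.01) and Cx3cr1 (0.13), markers of resting microglia, did not pass at 8 weeks in cortex in the authors' deposited table. Ccl6 (1.53), a chemokine, rose at 2 weeks with Rpl36al (3.93), whose reads can be shared with pseudogenes, in the authors' deposited table.

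Over the 14 microglia markers the cortex median was 0.34 at 3 days, with all 14 above 0 and 0 past the threshold in the authors' edgeR table (0 at an unadjusted p under 0.05 and 0 adjusted over the list alone). It was 0.30 at 2 weeks, 0.63 at 4 weeks, 0.69 at 8 weeks and 0.53 at 16 weeks. Of these markers 6, 0, 6 and 3 were higher at those times and 0 lower, and adjusted over the list alone 9, 9, 9 and 10 were higher. At 32, 40, 48 and 52 weeks the medians were -0.24, 0.14, 0.01 and 0.04. The 8 reactive astrocyte genes tested in cortex had medians of 0.46, 0.75, 0.77 and 0.50 at 2, 4, 8 and 16 weeks. Of them 2, 3, 4 and 1 were higher, and adjusted over the list alone 6, 6, 7 and 5. Over all 27 tables, 37 of 369 microglia marker values were higher and 0 lower, or 104 and 2 adjusted over the list alone. Reactive astrocyte genes had 24 of 207 higher and 1 lower (57 and 2 adjusted over the list alone). The list of general astrocyte markers had 0 of 324 higher and 2 lower in the authors' edgeR tables (8 and 6 adjusted over the list alone), with 31 at an unadjusted p under 0.05. Activated microglia and antigen presentation genes had 17 of 243 higher and 0 lower (49 and 4 adjusted over the list alone). Endothelial and mural markers had 0 of 324 past the threshold in the authors' edgeR tables, with 8 higher and 9 lower adjusted over the list alone and 43 at an unadjusted p under 0.05.

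**Figure D2:**
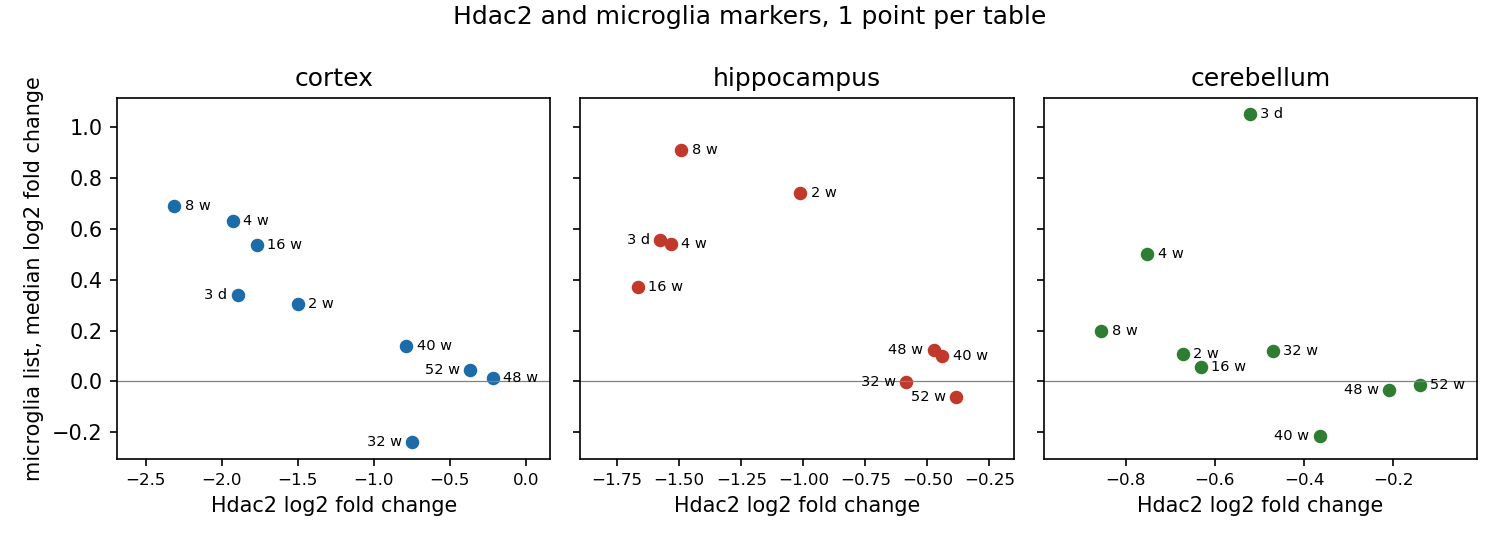
Hdac2 log2 fold change (x axis) and median log2 fold change of the microglia markers (y axis) in each of the 9 tables of cortex, hippocampus and cerebellum. The microglia median is highest in cerebellum at 3 days (1.05) and in hippocampus at 8 weeks (0.91).

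The lists were also set against Hdac2 over the 9 tables, in 12 relations. The microglia median was higher where Hdac2 was lower in cortex (r = -0.88, permutation p = 0.00302, adjusted p = 0.0181, and rho = -0.93, p = 0.000750, adjusted p = 0.00450), with r = -0.90 without the 2 farthest time points. Reactive astrocyte genes gave r = -0.96 in cortex (permutation p = 0.000369, adjusted p = 0.00443) and rho = -0.95 (p = 0.000353, adjusted p = 0.00423), with r = -0.97 without the 2 farthest. In hippocampus the microglia relation did not pass after adjustment (r = -0.77, permutation p = 0.0243, adjusted p = 0.0540, and rho = -0.65, p = 0.0666, adjusted p = 0.0998), with r = -0.82 without the 2 farthest. It did not pass in cerebellum either (r = -0.36, permutation p = 0.356, adjusted p = 0.427, and rho = -0.67, p = 0.0589, adjusted p = 0.0998), with r = -0.38 without the 2 farthest. Activated microglia genes passed in cortex (r = -0.83, permutation p = 0.00465, adjusted p = 0.0186, and rho = -0.92, p = 0.00131, adjusted p = 0.00525), with r = -0.88 without the 2 farthest, and the other 7 relations had adjusted p of 0.0533 or more. Hdac2 was nearer to 0 at later weeks, and in cortex the microglia, reactive astrocyte and activated microglia medians gave rho of -0.62, -0.68 and -0.72 with weeks (permutation p = 0.0857, 0.0503 and 0.0369, not adjusted), so a relation with Hdac2 is not separated from time.

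Myelin genes were lower in cortex at 2 weeks. Mbp (-0.90, FDR 0.0440), Mog (-0.63), Aspa (-0.68) and Bcas1 (-0.73) fell in the authors' deposited table. Lpar1, a lysophosphatidic acid receptor gene, fell by 1.12 there in the authors' deposited table. The 12 oligodendrocyte markers had a median of -0.64, with 11 lower and 0 higher, or 12 and 0 adjusted over the list alone. Immediate early genes, which neurons switch on with activity, differed in both directions. Of their 513 values over all tables, 36 were higher and 3 lower, or 73 and 34 adjusted over the list alone. Nr4a1 (1.42), Egr1 (1.02) and Nr4a3 (0.85) rose at 8 weeks in cortex in the authors' deposited table. At 16 weeks Egr2 (2.06), Nr4a1 (2.01), Arc (1.56) and Dusp1 (1.50) rose in cortex in the authors' deposited table. The median of the 20 immediate early genes was 0.67 at 8 weeks (8 higher, 13 adjusted over the list alone) and 1.18 at 16 weeks (7 higher, 16 adjusted over the list alone). At 32 and 40 weeks in cortex it was -0.22 and -0.18, with 0 and 1 lower, or 7 and 6 lower and 1 and 1 higher adjusted over the list alone. The red cell genes Alas2 (-1.18) and Hba-a1 (-1.09) fell at 16 weeks in cortex in the authors' deposited table, where the small RNA genes Rn7s2 (4.68) and Rn7s1 (2.72), which are near-identical copies, rose. These copies moved in both directions: Rn7s2 fell in cortex at 4 weeks (-3.80) and 32 weeks (-3.98) and rose at 40 weeks (4.51), in the authors' deposited tables. Rn7s1 rose in cortex at 40 weeks (3.85) and fell in hippocampus at 4 weeks (-0.76) and in cerebellum at 40 weeks (-4.03), in the authors' deposited tables.

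In cortex, Hdac2 passed at 32 weeks and not from 40 weeks on. Ttr (3.64), the choroid plexus transthyretin gene, and Tox (0.60) rose at 32 weeks in the authors' deposited table. Mid1 (-1.18) and the immediate early gene Egr3 (-0.81) fell at 40 weeks in the authors' deposited table. Lrrc17 (2.58) was the only call at 48 weeks in cortex, and at 52 weeks the somatostatin gene Sst (0.29) and the Y RNA gene Rny3 (0.46) rose, in the authors' deposited tables. The cerebellar granule neuron gene Gabra6 (-6.83) and Cnpy1 (-6.01) were lower at 52 weeks in cortex in the authors' deposited table. Over the 9 cortex time points, 4 of 54 cerebellar granule neuron marker values were lower and 0 higher, or 11 and 5 adjusted over the list alone. Whether unequal amounts of cerebellar tissue in the dissected pieces gave these differences was not tested, so they are not read as effects of the ASO.

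Cortex calls, as genes higher and lower at FDR 0.05, numbered 83 and 120 at 2 weeks, 49 and 8 at 4 weeks, 358 and 20 at 8 weeks and 92 and 46 at 16 weeks. They numbered 15 and 52 at 32 weeks, 29 and 13 at 40 weeks, 1 and 0 at 48 weeks and 2 and 40 at 52 weeks. At 3 days the authors' edgeR test called 0 genes, with 962 at an unadjusted p under 0.05 and 594 calls after LR was divided by the table's inflation. Inflation, the median LR over that of a chi-square with 1 degree of freedom, ranged from 0.375 to 2.70 over the 27 tables. With LR divided by it, the counts at 2, 8, 16 and 32 weeks in cortex were 55, 25, 14 and 2. Hdac2 then also passed at 3 days in cortex (adjusted p = 2.02e-06) and at 32 and 52 weeks in hippocampus (0.0205 and 0.0194).

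**Figure D3:**
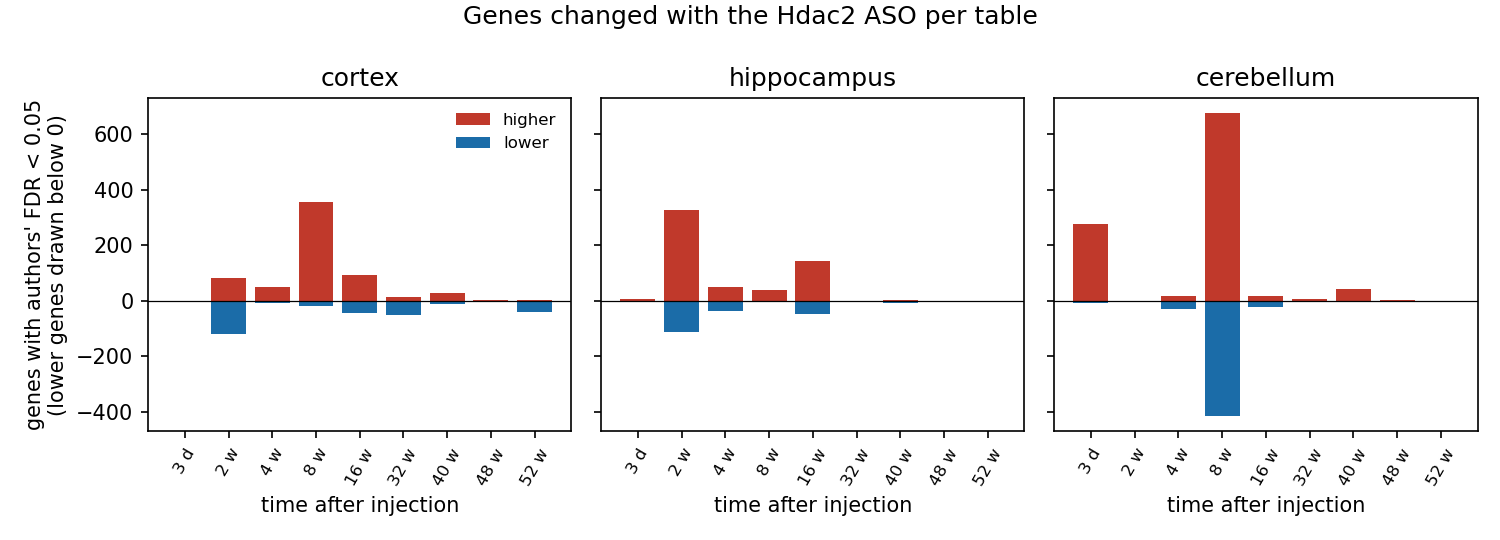
Number of genes higher (above 0) and lower (below 0) at the authors' FDR under 0.05 in each of the 27 tables, by tissue and time point. The largest counts are in cerebellum at 8 weeks, with 677 higher and 416 lower.

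In hippocampus, some microglial genes passed from 2 to 16 weeks too. Itgax (4.24) and Cd74 (2.50) rose at 4 weeks, Itgax (4.73), Clec7a (4.70), Lyz2 (3.38) and Cd74 (3.01) at 8 weeks, and Cd74 (2.72) and Lyz2 (2.35) at 16 weeks in the authors' deposited tables. C4b rose by 0.96, 1.94, 1.65 and 1.91 at 2, 4, 8 and 16 weeks in hippocampus in the authors' deposited tables. Gfap rose by 0.70 at 2 weeks and 0.95 at 8 weeks (FDR 0.0136) in hippocampus in the authors' deposited tables. The microglia median was 0.74, 0.54, 0.91 and 0.37 at 2, 4, 8 and 16 weeks, with 7, 3, 5 and 2 of 14 markers higher and 10, 9, 10 and 7 adjusted over the list alone (with 1 lower at 16 weeks). At 3 days it was already 0.56, with 0 markers past the threshold in the authors' edgeR table, 4 higher adjusted over the list alone and 7 at an unadjusted p under 0.05. From 32 weeks on it lay between -0.06 and 0.12. Reactive astrocyte medians at the same 4 early times were 0.45, 0.70, 0.77 and 0.75, with 3, 2, 2 and 4 genes higher and 5, 7, 5 and 6 adjusted over the list alone.

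At 2 weeks in hippocampus, choroid plexus genes led: Ttr (6.41), Cldn2 (5.53, a claudin of choroid plexus junctions), Kcne2 (5.52) and Folr1 (4.80) rose in the authors' deposited table. All 10 choroid plexus markers tested there were higher, with a median of 4.14, and 10 were higher adjusted over the list alone. The PHD finger gene Phf21b (-1.19) and the ribosomal protein gene Rps16 (-1.93) fell in the authors' deposited table at 2 weeks. At 16 weeks Fos (1.87), Dusp1 (1.63) and Arc (1.30) rose in hippocampus in the authors' deposited table, and the immediate early list had a median of 0.95 with 8 of 20 higher (16 adjusted over the list alone). Hbb-bt (-1.48), Alas2 (-1.41) and Hba-a1 (-1.36) fell at 16 weeks in hippocampus in the authors' deposited table. Dcn (-0.95), the decorin gene of fibroblasts, fell at 8 weeks, and Ighm (-1.11), an immunoglobulin heavy chain gene, fell at 52 weeks in the authors' deposited tables. Lrrc17 (2.20) and Snora78 (1.36) rose at 3 days, and Ahnak (0.44) rose while Rny3 (-0.89) fell at 40 weeks in the authors' deposited tables.

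Hippocampal calls, higher and lower, numbered 8 and 1 at 3 days, 328 and 113 at 2 weeks, 50 and 37 at 4 weeks, 38 and 3 at 8 weeks and 144 and 48 at 16 weeks. There were 2 and 8 at 40 weeks and 0 and 2 at 52 weeks. The authors' edgeR test called 0 genes at 32 and 48 weeks, with 987 and 1470 at an unadjusted p under 0.05, and 40 calls at 32 weeks with LR divided by inflation. With that division the counts at 2, 4, 8, 16 and 52 weeks were 8, 11, 1022, 8 and 110.

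In cerebellum at 3 days the developmental patterning gene Hoxb5 (9.42), Prph (7.84, the peripherin filament of motor neurons) and Slc5a7 (6.17, the choline transporter) rose, and Wipf3 (-1.37) fell, in the authors' deposited table. C4b (2.03), Spp1 (2.38) and C1qb (1.37) also rose at 3 days in cerebellum in the authors' deposited table. The oligodendrocyte median was 1.55 at 3 days (6 of 12 higher, 11 adjusted over the list alone). Choroid plexus genes were lower at 4 and 8 weeks: Ttr (-5.55) and Sostdc1 (-6.39) fell at 4 weeks, and Ttr (-7.33), Sostdc1 (-6.81), Folr1 (-6.05) and Kl (-3.64) fell at 8 weeks in the authors' deposited tables. Of the 9 choroid plexus markers tested, 8 were lower at 4 weeks and 9 at 8 weeks, with 9 and 9 lower adjusted over the list alone and medians of -2.27 and -2.72.

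Microglial genes were higher in cerebellum at 8 weeks too, with Lyz2 at 1.08, Cd68 at 0.91, Tyrobp at 0.64 and C1qa at 0.58 in the authors' deposited table. The 13 microglia markers had a median of 0.20 there (4 higher, 5 adjusted over the list alone), beside the lower choroid plexus markers. It was larger at 3 days (1.05, with 1 higher and 10 adjusted over the list alone) and at 4 weeks (0.50, with 0 past the threshold in the authors' edgeR table, 11 higher adjusted over the list alone and 11 at an unadjusted p under 0.05). Among activity genes, Nr4a3 (1.45) and Spry4 (1.14, a feedback inhibitor of growth factor signalling) rose at 8 weeks, and Fos (1.88), Nr4a3 (1.69) and Nr4a2 (1.59) rose at 16 weeks in cerebellum in the authors' deposited tables. The 17 immediate early genes tested had medians of 0.44 and 0.53 at these times, with 7 and 6 higher and 11 and 10 adjusted over the list alone. At 48 weeks Nr4a1 (-0.98) fell, and at 52 weeks the synaptic vesicle gene Sv2c (-0.63) fell, in cerebellum in the authors' deposited tables. Klk1b22 (-5.05), of a family of near-identical kallikrein genes, and Hbb-bt (-1.46) fell at 16 weeks in the authors' deposited table. Myh4 (8.88), a muscle myosin gene, rose at 4 weeks in cerebellum in the authors' deposited table.

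Cerebellar calls, higher and lower, numbered 278 and 7 at 3 days, 17 and 29 at 4 weeks, 677 and 416 at 8 weeks and 18 and 21 at 16 weeks. They numbered 7 and 0 at 32 weeks, 44 and 6 at 40 weeks, 3 and 1 at 48 weeks and 0 and 2 at 52 weeks. At 2 weeks the authors' edgeR test called 0 genes, with 639 at an unadjusted p under 0.05 and 86 calls after LR was divided by inflation. With that division the counts at 3 days and at 8, 16 and 40 weeks were 0, 44, 12 and 0. In 10 of the 27 tables, of which 2 are from cortex, 4 from hippocampus and 4 from cerebellum, 1 gene (CT010467.1 or mt-Rnr2, which hold ribosomal RNA sequence) took over 10% of the summed CPM (counts scaled to library size). These were cortex at 40 and 48 weeks, hippocampus at 3 days and 40, 48 and 52 weeks, and cerebellum at 3 days and 32, 40 and 48 weeks. AY036118 (8.01) and CT010467.1 (6.68) rose with Hdac2 ASO in cerebellum at 32 weeks in the authors' deposited table.

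**Figure D4:**
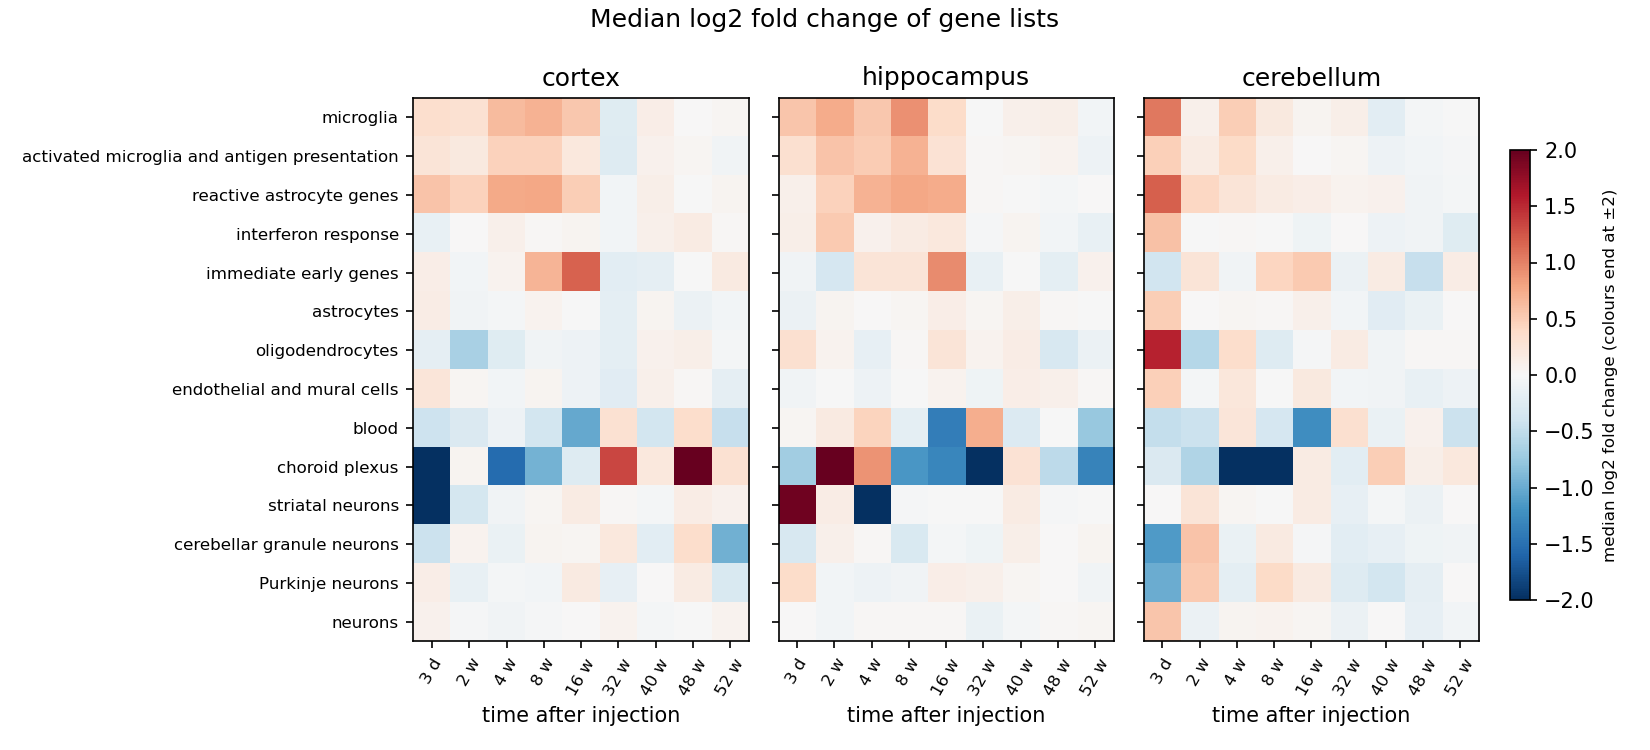
Median log2 fold change of 14 gene lists in each of the 27 tables, as a heat map by tissue and time point, with colours ending at -2 and 2. Microglia and reactive astrocyte lists are above 0 in cortex and hippocampus from 2 to 16 weeks, and the choroid plexus list takes values of both signs, such as 4.14 in hippocampus at 2 weeks and -2.72 in cerebellum at 8 weeks.

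The last question was which genes changed on average over the year. Lyz2, C4b and Gpnmb had averages above 0 in cortex and hippocampus, and Hdac2 below 0 in all 3 tissues. None passed the limma test on the 9 log2 fold changes, which called 0 genes in cortex, hippocampus and cerebellum, with 1203 of 14151, 608 of 13801 and 196 of 14403 at an unadjusted p under 0.05. Hdac2 itself had adjusted p of 0.278, 0.588 and 0.156 in that test. In simulated data the test found 93.0% or more of constant changes. Of changes of log2 size 1 that faded over time as Hdac2's did, it found 7.91% in cortex, 11.6% in hippocampus and 24.5% in cerebellum, against 42.8%, 46.6% and 20.1% at size 0.5 and 0%, 0.152% and 2.27% at size 2. Limma without the robust option found 99.6%, 98.4% and 89.1% of fading changes of size 1, and it also called 0 genes in each tissue on the real tables, with 1209, 607 and 197 at an unadjusted p under 0.05. At size 0.5 it found 82.4%, 69.0% and 34.9%, so smaller fading changes can be missed, in cerebellum most of all. On the real tables Hdac2 did not pass this limma form either (adjusted p = 0.162, 0.132 and 0.178). The simulated genes were drawn independently, with the same fading shape in all tissues. That shape was steeper than the fading of Hdac2, which in cerebellum went from -0.63 at 16 weeks to -0.47 at 32 weeks. The shares found need not hold for changes that fade as Hdac2's did. The 0 calls therefore do not show that larger fading changes are absent. The sum of the signed roots of LR, a test that treats the tables as fixed and takes the authors' LR at face value, called 232 genes higher and 138 lower in cortex, 75 and 8 in hippocampus and 10 and 15 in cerebellum. With LR divided by inflation it called 79 and 34, 38 and 5, and 4 and 8, and 7, 22 and 66 of 100 random assignments of signs to the tables, the real one included, gave as many genes as the undivided sum. Without 8 weeks the undivided sum called 198 genes in cortex and 7 in cerebellum, and without 4 weeks and 52 weeks it called 13 and 44 in cerebellum.

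By the sum with LR divided by inflation, the cortex genes with the highest average, among those with its sign at 7 or more time points, were Lyz2 (1.23), C4b (1.17), Gpnmb (1.02), Cd74 (0.86), Mpeg1 (0.73, a pore-forming protein of macrophages), Gfap (0.67), the lactase gene Lct (0.61), Cd68 (0.61) and Tyrobp (0.55). The lowest in cortex were Hdac2 (-1.28), AY036118 (-0.97), Cdr1 (-0.60), Lpar1 (-0.39), Pde1c (-0.38, a phosphodiesterase), D7Ertd443e (-0.36), Hba-a1 (-0.34), St18 (-0.33), mt-Tp (-0.33), Fam135b (-0.33), Ermn (-0.28) and Bcas1 (-0.27). AY036118, at a mean logCPM of 13.7, ranged from -3.44 to 2.32 over the cortex time points. It rose beside CT010467.1, which holds ribosomal RNA sequence, in cerebellum at 32 weeks (8.01 and 6.68), and the cause was not tested. In hippocampus the highest were Lyz2 (1.47), C4b (0.85), Gpnmb (0.79), Mpeg1 (0.73), Cd84 (0.67) and C3ar1 (0.65), and the lowest were Hdac2 (-1.02) and Fam135b (-0.34). In cerebellum they were Lars2 (1.47), whose reads can be shared with ribosomal RNA sequence, Lyz2 (0.54), the mitochondrial tRNA gene mt-Te (0.33), Hdac2 (-0.51) and Clic6 (-0.50). Hdac2 and Lyz2 were called in all 3 tissues. Lct in cortex (adjusted p = 0.0469 by the divided sum) and Clic6 in cerebellum (0.0463) were close to the threshold. Some of these averages rest on 1 time point. Without 3 days Lct was at 0.35 and Pde1c at -0.24 in cortex, and in cerebellum Lars2 was at 0.90 without 32 weeks and mt-Te at 0.21 without 40 weeks. The losses that follow are those of the undivided sum. Losses by the divided sum, which named these genes, are not given here. More calls may be lost by it, since its adjusted p was larger for calls near the threshold. By the undivided sum Lct was at 0.00553 in cortex and Clic6 at 0.000161 in cerebellum. In cortex the call of mt-Tp was lost without 2 weeks (adjusted p = 0.0517), that of Hba-a1 without 16 weeks (0.0679) and that of AY036118 without 32 weeks (0.183) or 52 weeks (0.0691). In cerebellum the call of Lars2 was lost without 48 weeks (adjusted p = 0.235), that of Clic6 without 4 weeks (0.0994) or 8 weeks (0.626) and that of mt-Te without 4 weeks (0.550) or 40 weeks (0.0588). Lars2 ranged from -1.98 at 8 weeks to 6.02 at 32 weeks in cerebellum, and it was lower in cortex at 32 weeks (-2.38, FDR 0.00256) and in hippocampus at 4 weeks (-3.34, FDR 3.06e-19), in the authors' deposited tables.

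Lists were compared with all other genes by camera with a preset correlation of 0.01, over 84 tests of list and tissue, of which 25 passed an adjusted p of 0.05. Microglia markers were higher in cortex (adjusted p = 7.84e-08), hippocampus (5.44e-16) and cerebellum (6.82e-10). With an estimated correlation their p were 0.0838, 0.0141 and 0.0531 (adjusted p = 0.563, 0.535 and 0.557). In cerebellum the mean of the 9 microglia medians was 0.20, and without 3 days, when oligodendrocyte markers were at 1.55, it was 0.09 (camera adjusted p = 0.000115). Markers of other cell types were also called higher there by camera. They were oligodendrocyte precursors (adjusted p = 0.000759), meninges and fibroblasts (0.000300) and endothelial and mural cells (0.0418). Reactive astrocyte genes were higher in cortex (adjusted p = 5.50e-07), hippocampus (9.48e-07) and cerebellum (0.000386), and these calls were lost under an estimated correlation (p = 0.0382, 0.0366 and 0.0187, each with an adjusted p of 0.535). Their mean of medians in cerebellum was 0.25, and 0.13 without 3 days (camera adjusted p = 0.00766). Oligodendrocyte markers were lower in cortex (adjusted p = 1.90e-06), and choroid plexus markers lower in cerebellum (adjusted p = 0.000166). Both calls were lost with an estimated correlation (p = 0.110 and 0.154, each with an adjusted p of 0.563). The mean of medians of oligodendrocyte markers in cortex was -0.14, and -0.08 without 2 weeks (camera adjusted p = 0.000694). That of choroid plexus markers in cerebellum was -0.57, and -0.36 without 4 weeks (camera adjusted p = 0.0124) and -0.30 without 8 weeks (0.0735), where the call was lost. In cerebellum oligodendrocyte markers were called in the other direction, higher (adjusted p = 0.00195), which was also lost with an estimated correlation (p = 0.298, adjusted p = 0.735). That direction came from 3 days alone: the mean of medians was 0.13, and -0.05 without that time point (camera adjusted p = 0.642). It was 0.22 without 2 weeks (0.000107). By camera, immediate early genes were higher in cortex (adjusted p = 0.000446), which was lost under an estimated correlation (p = 0.265, adjusted p = 0.735). The call was also lost without 16 weeks, where the mean of medians went from 0.20 to 0.07 (camera adjusted p = 0.0842). Of the 25 calls, 15 changed without some 1 time point and 10 did not, among them microglia and reactive astrocyte genes in each tissue and oligodendrocyte markers in cortex. None of the 25 calls held with an estimated correlation, for which the smallest adjusted p over the 84 tests was 0.535, or with fry (0.542) or the exact sign-flip test of list medians (0.459). The smallest sign-flip p over 9 time points is 0.0039, so 1 list alone could not pass after adjustment over 84 tests. Unadjusted sign-flip p in cortex, hippocampus and cerebellum were 0.0352, 0.0156 and 0.141 for microglia and 0.0234, 0.0391 and 0.0273 for reactive astrocyte genes. For 6 of the lists (microglia, activated microglia, reactive astrocytes, oligodendrocytes, immediate early genes and choroid plexus) the medians were compared between tissues, and none of the 18 exact sign-flip tests passed (smallest p = 0.043, adjusted p = 0.519).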

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

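The Hdac2 differences between tissues were planned, with the form of their exact test chosen later, and the other tests in this part were chosen after the results they measure had been seen. The average Hdac2 log2 fold change differed between tissues in 3 of 3 pairs by an exact sign-flip test over the 9 time points. The differences were -0.26 for cortex minus hippocampus (7 of 9 time points), -0.77 for cortex minus cerebellum and -0.51 for hippocampus minus cerebellum (9 of 9 each). The first did not pass without any 1 of 5 time points, with a range of -0.33 to -0.19. Uptake of the ASO by tissue was not analysed here, and no explanation for these differences was tested.

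Some microglia markers were higher in cortex at 2, 8 and 16 weeks and in hippocampus at 2, 4, 8 and 16 weeks. A lower share of neurons would raise the markers of every other cell type alike. In cortex at 2 weeks 11 of 12 oligodendrocyte markers were lower (median -0.64), but the highest endothelial or mural marker (0.38) lay above the microglia median (0.30). There the oligodendrocyte markers alone argue against a lower share of neurons as the whole cause, and why they fell was not tested. The microglia median exceeded the highest endothelial or mural marker by at least 0.28 in cortex at 8 and 16 weeks and by at least 0.16 in hippocampus at 2, 4 and 8 weeks. These time points were picked because microglia markers passed, which favours such an excess, and its spread is unknown. Oligodendrocyte medians, not used in that choice, were -0.08 and -0.11 in cortex at 8 and 16 weeks. They were 0.07, -0.16 and 0.02 in hippocampus at 2, 4 and 8 weeks. Markers of other cell types thus did not rise alike, which argues against a lower share of neurons as the whole cause at those times. In hippocampus at 16 weeks (excess 0.10) all oligodendrocyte markers were above 0 too and it stays open. Over all 9 tables microglia minus endothelial medians did not pass (0.28 and 0.36, 7 of 9 each, exact sign-flip p = 0.0156 and 0.0391, adjusted p = 0.0573 over 4 tests). More blood in the tissue would raise red cell genes, but the highest of 5 was -0.18 in cortex at these times and -0.16 in hippocampus at 8 and 16 weeks, while in hippocampus it reached 0.48 at 2 weeks (median of the 5 genes 0.03) and 0.52 at 4 weeks (median 0.41), where blood stays open, and over all 9 tables microglia minus blood medians did not pass (0.54 and 0.50, exact sign-flip p = 0.0430 and 0.0625, adjusted p = 0.0573 and 0.0625). The markers may follow the Hdac2 decrease, since late minus early medians were -0.48 in cortex and -0.68 in hippocampus, but 3 against 3 tables cannot give an exact permutation p below 0.1, and a response to the oligonucleotide itself is untested. In hippocampus choroid plexus markers were also higher at 2 weeks (Ttr 6.41), and striatal neuron markers had a median far below 0 at 4 weeks. Whether unequal dissection adds to the microglia rise was not tested.

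Choroid plexus markers differed by a list median beyond 1 in log2 in 11 of 27 tables, 3 of them higher and 8 lower. Unequal amounts of choroid plexus in the dissected pieces would give both directions, and the rarer direction was seen in 3 tables, up to 4.14 in hippocampus at 2 weeks. An effect of the ASO in 1 direction in all tissues is not borne out by these signs, and no tissue's medians passed an exact sign-flip test (smallest p = 0.215). An effect in cerebellum alone, where the medians at 4 and 8 weeks were -2.27 and -2.72, stays open.

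In cerebellum at 3 days oligodendrocyte markers had a median of 1.55, while granule neuron and Purkinje neuron markers had medians of -1.13 and -0.99, with 0 of these neuron markers past the threshold in the authors' edgeR table. Oligodendrocyte minus granule neuron markers gave 2.67. This is consistent with more white matter or brainstem in the pieces from Hdac2 ASO mice, as are Hoxb5 (9.42) and Prph (7.84) in the authors' deposited table. With no value per mouse, the number of mice that carry the difference is unknown. No biological explanation was tested.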

How the results depend on the processing

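Here the tests chosen after the results were seen are all settings except leaving out time points for averages, the filters of at least 1 count, the estimated correlation and fry. With LR divided by each table's inflation, gene counts became 594, 55, 25, 14 and 2 in cortex (3 days, 2, 8, 16 and 32 weeks), 8, 11, 1022, 8, 40 and 110 in hippocampus (2, 4, 8, 16, 32 and 52 weeks) and 0, 86, 44, 12, 0 and 2 in cerebellum (3 days, 2, 8, 16, 40 and 48 weeks). Factors under 1 raise counts by construction and factors over 1 lower them. With only genes of logCPM at least 1, counts became 223, 253 and 4 in cortex (16, 32 and 48 weeks), 732, 183, 328, 1, 26 and 1 in hippocampus (2, 4, 16, 32, 40 and 52 weeks) and 74 and 1 in cerebellum (16 and 52 weeks). With genes of at least 1 count they became 105 and 3 in cortex (32 and 48 weeks) and 7 in cerebellum (48 weeks). In these 2 settings fewer genes are adjusted for. Hdac2 kept its side of the threshold in 27 of 27 tables under both filters and in 24 with LR divided by inflation, where it also passed in cortex at 3 days (adjusted p = 2.02e-06) and in hippocampus at 32 weeks (0.0205) and 52 weeks (0.0194). Averages over time gave 0 genes by limma with table weights, without the robust option and without any 1 time point. The sum of signed roots gave 370, 83 and 25 genes in cortex, hippocampus and cerebellum, and 113, 43 and 12 with LR divided by inflation (factors under 1 left at 1). In hippocampus limma on signed roots gave 1 gene (Hdac2), and limma without the logCPM filter gave 1. The cause was not tested. The Hdac2 average ranged from -1.41 to -1.15 in cortex, -1.10 to -0.94 in hippocampus and -0.56 to -0.47 in cerebellum without any 1 time point (exact sign-flip p = 0.0078 each). Without tables led by 1 gene it was -1.26 in hippocampus and -0.61 in cerebellum, each with the exact p of 0.0625 that is the smallest 5 tables allow. Cortex minus hippocampus ranged from -0.33 to -0.19 without any 1 time point, and exact p from 0.0156 to 0.0703. Of 84 list tests, the 25 calls were lost with an estimated correlation, with fry and with sign-flip tests, and without tables led by 1 gene 11 were gained and 4 lost. Without some 1 time point 15 of the 25 changed. No paired analysis was possible because the tables hold no value per mouse: mice could not be paired, and the comparisons between tissues pair time points only. Not run for the same reason were the fit of 54 libraries, the replicate block, DESeq2 size factors and its test, limma-voom, duplicateCorrelation, other pseudocounts, leaving out replicates and the interaction over time.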

Other observations

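The tests of random sign assignments for limma were chosen after an earlier form of their result had been seen. In some forebrain tables, markers of striatal neurons had list medians far from 0, of both signs, without passing the authors' threshold. In cortex at 3 days their list median was -2.30, with Drd1 (-2.62) and Drd2 (-3.69) in the authors' deposited table, and 0 of 8 passed by edgeR, or 8 lower adjusted over the list alone. In hippocampus the median was 1.95 at 3 days (7 higher adjusted over the list alone) and -2.06 at 4 weeks (7 lower), where Adora2a was at -3.72 (FDR 0.0505) in the authors' deposited table.

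The sum of signed roots called 370, 83 and 25 genes in cortex, hippocampus and cerebellum. When the signs of whole tables were assigned at random, 7, 22 and 66 of 100 assignments, the real one included, gave as many genes, with 1060, 1136 and 1682 as the highest others. Chance is therefore not excluded for these counts. Assignments with several times the real count point to a structure of the tables, which was not traced further. Without 8 weeks the counts were 198 in cortex and 7 in cerebellum, and without 4 weeks and 52 weeks cerebellum gave 13 and 44. For limma, which called 0 genes, 100 of 100 assignments gave as many in each tissue, an outcome that a real count of 0 fixes, so this says nothing about chance. The highest others were 7, 104 and 89.

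In simulated data the sum of signed roots found 100% of fading changes of log2 size 1 in cortex and hippocampus and 99.9% in cerebellum. Of all its calls there, 4.72%, 5.96% and 4.13% were false. Simulated scores were scaled by the spread they were drawn with, and genes were independent. The authors' LR has an inflation from 0.375 to 2.70, so these shares need not hold for the real tables.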
